A study of Mus musculus with 4 samples.

How the data were processed

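Chromatin immunoprecipitation with sequencing (ChIP-seq) of transketolase, an enzyme of the pentose phosphate pathway, was available for the retina of Tet-opsin-VEGFA mice with and without induction of the transgene. Per the series text, 2 retinas were collected for each condition. Each condition had 1 ChIP library and 1 input library, 4 libraries in all, and each peak list compared a ChIP library with the input of its own condition, without pooling across conditions. Per the labels' protocols, tissue was crosslinked with methanol, sonicated and immunoprecipitated with an antibody to transketolase.

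Reads were aligned with Bowtie2 2.2.7 to the mouse build mm10 (GRCm38), and FastQC was also named, per the submitters' processing notes. The peak caller was not given in the sources used here. The tag counts per peak were deposited as whole numbers of tags in the ChIP library, per the file headers, and were not normalized by the authors. The fold enrichment of each peak was deposited by the authors as a ratio of ChIP tags to a background, per the file headers, and how that background was estimated was not given in the sources used here. The strength of each peak was deposited as a score, 10 times the −log10 p-value, per the file headers, and it is given here as −log10 p. The false discovery rate was deposited by the authors as a percent for each peak. The authors' fold, score and false discovery rate were used to describe, rank or filter peaks within a list. Exceptions were the correlation of folds over shared pairs, the choice of pairs by the lower fold of each, and the choice of gene list members by fold over both lists, where the backgrounds of the lists differ. The authors' annotation placed each peak relative to RefSeq transcripts, on separate lines for each transcript, and peaks were counted once here. In the deposited values, promoter peaks had their centre within 2 kb of a transcription start site, upstream peaks lay from 2 to 20 kb before it, and the rest were exon, intron or intergenic. A peak inside a gene could be assigned by the authors to the start site of a neighbouring gene, so peaks inside the endoplasmic reticulum (ER) stress genes were also found by position. A further 3 sheets held no values and were not used here.

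Total library depth was unknown, because the files gave only tags within peaks. The positions were compared with a RefSeq gene table of GRCm38: 99.7% of control and 99.8% of induced transcripts were found there, and the listed start sites fell within the gene for 99.1% and 99.0%. Pseudogenes and gene spans were taken from that table. It held no strand, so the planned comparison of start sites with random placement was replaced by the share of peaks near either gene end, within 2 kb. Chromosome lengths were not at hand, and random placement used the stretch from the first to the last gene of each chromosome.

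Shares were given with 95% Wilson intervals. Intervals cover counting error only, not the spread between animals. Lists were compared with bedtools 2.31.1 at an overlap of at least 1 bp, against 100 random placements on the same chromosome. Gene lists were compared with 10000 random lists of equal size, matched on 10 classes of gene length and drawn from 26219 genes with a RefSeq transcript on the autosomes, X and Y. The share of random lists with at least as many members is a description of these libraries. With 1 ChIP library per condition, no test between conditions was possible and no p-value was given. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated data, lists placed at random gave 0.984 times the expected overlap. Of 1000 overlaps planted among 18267 peaks, 990 were recovered. Among simulated lists of 48 genes, 2.5% of unplanted lists and 100% of lists with 8 planted members reached the top 5%. The 8 members were added to those hit at random, and smaller excesses were not simulated.

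The groups, the designs and the gene lists were set before the data were examined. The lists covered ER stress, the pentose phosphate pathway, glycolysis, phototransduction, retinal transcription factors, VEGF and hypoxia, antioxidant response, complement, apoptosis, oxidative phosphorylation, chromatin and nuclear metabolic enzymes, cytosolic ribosomal proteins and olfactory receptors. They also covered markers of Müller glia, pigment epithelium, microglia, endothelial cells and pericytes, bipolar cells, amacrine and ganglion cells, and liver. The ribosomal and olfactory lists were defined by a pattern of gene symbols. They were first matched through gene synonyms too, which took in unrelated genes such as Ubb, and this was corrected to symbols alone after results had been seen. The correction took the ribosomal list from 90 to 82 genes, and its members with an exon or promoter peak of at least 20-fold from 12 to 9.

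Named genes followed a rule: Tkt and Vegfa, the 10 genes of highest promoter fold in each list, every ER stress and pentose phosphate member with a promoter peak up to 10 per list, and up to 4 members of each other list. The 5 overlapping pairs with the highest lower fold and the 5 strongest unshared peaks of each list were also named. Some genes that the rule takes are not reported here. Exon peaks, peaks inside ER stress genes, the boundary of 20-fold and the pseudogene overlap were chosen after the values were seen. The parent gene of a pseudogene was taken from its symbol, as the part before the suffix -ps, and pseudogenes without that suffix had no parent here. The settings chosen before the values were seen were a −log10 p of at least 10, a fold of at least 5, the autosomes, X and Y alone, equal numbers of top peaks, promoters of 1 or 3 kb, an overlap of 50% of both peaks, summits within 200 bp, and other random lists. The deposited false discovery rate had at most 2 decimals of a percent, too coarse for the q-value threshold first intended, so the −log10 p was used in its place. Keeping only peaks with a false discovery rate listed as 0, leaving out pseudogene peaks or peaks of at least 20-fold, and shifting peaks locally by 10 to 100 kb, were chosen after seeing the data.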

Results

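Transketolase occupancy was profiled by ChIP-seq in the retina of mice carrying an inducible VEGFA transgene, a VEGF-overexpressing model of age-related macular degeneration. The design addressed where transketolase lay on chromatin with and without induction, in a study concerned with ER stress. Noninduced (control) and induced retinas each gave 1 ChIP library, called against 1 input library. The control list held 18267 peaks with 351574 tags over 13.5 Mb, a mean of 19.2 tags per peak. The induced list held 30791 peaks with 472950 tags over 17.1 Mb, a mean of 15.4 tags per peak. There were no replicates, so no difference between the lists can be set against a spread between animals.

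Neither list placed a peak at Tkt itself. Vegfa held no assigned peak in the control list and 4 in the induced list. Its promoter peak (chromosome 17, 46031698 to 46032138, mm10) held 11 tags at 8.59-fold, and an exon peak held 17 tags at 6.27-fold. The lowest tag count listed was 14 in the control and 10 in the induced list, so the Vegfa promoter peak lay near the floor of its list.

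The most enriched promoters in the induced list belonged to Ubb (292.07-fold, 847 tags), Yipf4 (220.13-fold), Mir682 (215.83-fold), Gm5643 (213.68-fold), Ubb-ps (204.45-fold), Defb7 (190.06-fold), Pabpc1 (176.1-fold), Cfl1 (157.34-fold), Slc25a5 (149.26-fold) and Reps2 (142.81-fold). Of these peaks, those of Yipf4, Mir682, Gm5643, Ubb-ps, Defb7 and Reps2 overlapped annotated pseudogenes. Those of Ubb, Pabpc1, Cfl1 and Slc25a5 were centred 720, 326, 1987 and 1572 bp downstream of the start site. In the control list the leading promoters were Sspn (17.41-fold, 67 tags), Ftl1 (16.62-fold), Ubb (15.74-fold), Defb7 and Rplp2-ps1 (12.71-fold each), Ubb-ps (12.22-fold), Det1 (11.73-fold), Mir692-2 and Mir692-3 (11.24-fold, from a shared peak) and Cep43 (10.75-fold). The gene table placed Mir692-3 under that shared peak and Mir692-2 elsewhere. Ubb encodes ubiquitin, and Ubb, Ubb-ps and Defb7 were among the leading promoters of both lists. The median fold was 5.86 in the control and 8.59 in the induced list, and the highest was 27.86 and 456.36. Fold is relative to a background that differed between the lists: the typical step between the most common fold values was 0.49 in the control and 1.075 in the induced list. The backgrounds read from these steps differed 2.19-fold. That is more than the 1.47-fold difference between the median folds. It is less than the 16.4-fold difference between the highest folds, which lay at different sites. With 1 library per condition and unknown depth, a higher fold in the induced list is still not evidence of more binding.

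**Figure D1:**
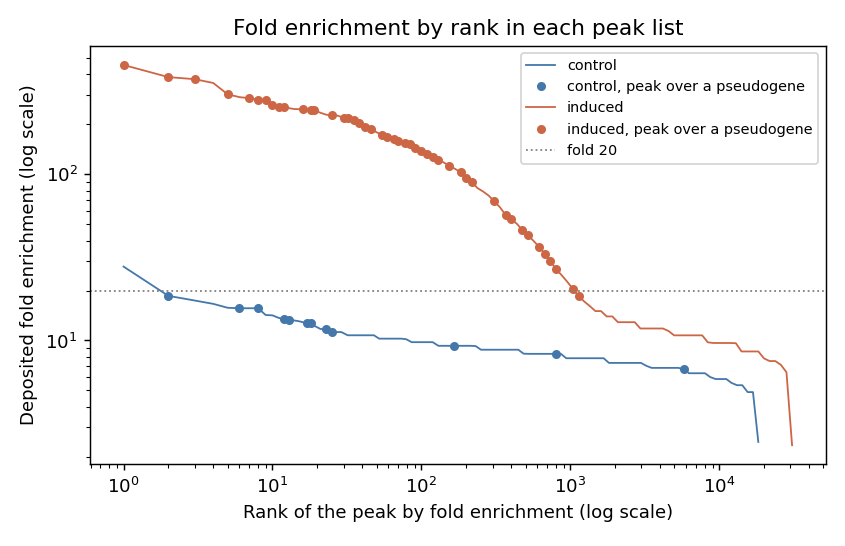
Deposited fold enrichment (log axis) against the rank of the peak (log axis) in the control and induced lists, drawn at a sample of ranks, with points where the drawn peak overlapped an annotated pseudogene. At least 20-fold enrichment was listed for 1 control peak and 1073 induced peaks.

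Induced peaks of at least 20-fold lay largely at pseudogenes and exons. They numbered 1073 (3.48% of peaks) and held 20.7% of the tags in induced peaks. Of them, 63.0% (60.1 to 65.8) overlapped an annotated pseudogene, against 2.76% of the weaker induced peaks and 1.43% under random placement. They touched 661 of 10429 annotated pseudogenes. Exons held 13.98% and promoters 12.8% of these peaks. Strong exon peaks outside pseudogenes were at Actb (247.64-fold, 510 tags), Ptma (228.72-fold), Tubb5 (226.57-fold) and Tuba1b (206.17-fold), genes of actin, prothymosin and tubulin. Among the 50 strongest control peaks, 26% (15.9 to 39.6) overlapped a pseudogene, against 1.5% under random placement.

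Over all peaks, promoters held 8.47% (8.07 to 8.88) of control and 5.77% (5.52 to 6.04) of induced peaks. Exons held 2.10% and 3.13%, introns 34.2% and 30.8%, upstream regions 13.7% and 14.5%, and intergenic regions 41.5% and 45.8%. Gene ends were favoured in both lists, with 11.5% of control peaks within 2 kb of one against 6.73% at random, and 10.2% of induced peaks against 6.65%. Chromosome X was sparse, with 105 control and 421 induced peaks, or 0.615 and 2.47 per Mb against 7.43 and 12.4 per Mb on the autosomes. Chromosome Y held 11 and 45 peaks. The sex of the animals and the coverage of chromosome X were unknown here. Its lower counts are therefore not evidence of less binding. The promoter shares depended on the threshold: at a −log10 p of at least 10 they were 18.3% and 11.5%.

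**Figure D2:**
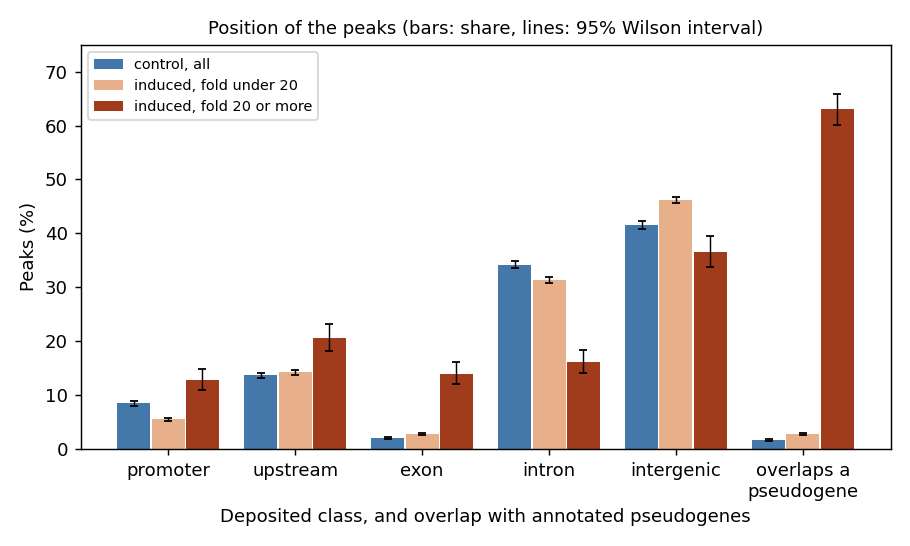
Percent of peaks in each deposited class, and percent overlapping annotated pseudogenes, for all control peaks and for induced peaks under and from 20-fold, with 95% Wilson intervals. The pseudogene share was 63.0% for induced peaks of at least 20-fold and 2.76% for the weaker ones.

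ER stress genes, the subject of the study's title, held promoter peaks at 4 of 48 members in the control and 6 of 48 in the induced list. Random lists averaged 3.20 and 3.51, and 39.9% and 13.5% of them held as many. With equal numbers of top peaks from each list, the induced count was still 6, which 2.35% of random lists reached. With centres within 1 kb of the start site it was 3, reached by 32.5%, and at a −log10 p of at least 10 it was 1, reached by 33.0%. Ero1a, an ER oxidase, held a promoter peak in both lists (18 tags at 5.86-fold in control, 13 tags at 7.52-fold in induced), but the peaks did not overlap. Calr and Vcp, a chaperone and an ATPase of protein degradation, and Bbc3 held one in the control list, at 5.86-fold, 6.84-fold and 5.38-fold. Atf4 and Atf3, stress transcription factors, Selenos, Edem1 and Sdf2l1 held one in the induced list. The Atf4 peak (chromosome 15, 80256180 to 80256928) was the strongest at 38.66-fold with 49 tags, and the other 4 lay between 8.59-fold and 10.74-fold. The centre of the Atf4 peak lay 1370 bp downstream of the start site. Leaving out peaks of at least 20-fold left 5 induced members.

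Stronger induced peaks lay outside the promoters of ER stress genes. Hspa5, the gene of the chaperone BiP, held an induced exon peak (chromosome 2, 34775485 to 34776461) of 82.87-fold with 266 tags. An induced peak of 41.88-fold with 48 tags also lay within Hspa5, although it was assigned to the upstream region of Gapvd1. The control list held an exon peak at Hspa5 (34775293 to 34776339) of 7.82-fold with 29 tags. By position, 10 induced peaks of at least 20-fold lay within 5 of the 48 genes, namely Atf4, Hsp90b1, Hspa5, Manf and Pdia4. Hsp90b1, another ER chaperone, held 3 of them, an intron peak of 39.73-fold and exon peaks of 24.7-fold and 23.62-fold. Outside the genes, induced peaks of at least 20-fold were assigned upstream of Hyou1 (52.62-fold, 83 tags, over a pseudogene) and to intergenic sites nearest Edem1 (27.92-fold) and Herpud1 (20.4-fold, over a pseudogene). Exon or promoter peaks of at least 20-fold were assigned to 3 of 48 ER stress genes, against 9 of 82 cytosolic ribosomal protein genes.

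**Figure D3:**
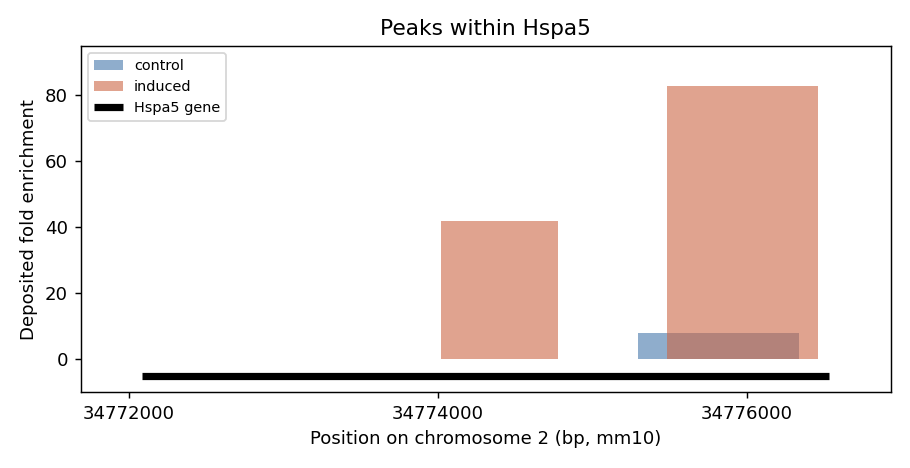
Peaks within Hspa5 on chromosome 2 (position in bp, mm10), with height as deposited fold enrichment and width as peak length, and the gene drawn as a black bar. The induced exon peak reached 82.87-fold and the overlapping control peak 7.82-fold, values that rest on different backgrounds.

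No pentose phosphate gene of 14 held a promoter peak in either list, while any assigned peak was found at 2 in the control and 7 in the induced list. Among 21 glycolysis genes, promoter peaks were listed at 0 in the control and 3 in the induced list, at Aldoa (11.63-fold), Eno1 (10.74-fold) and Pfkm (8.59-fold). Among 36 oxidative phosphorylation genes the counts were 5 and 6, with Atp5b in both, and 7.45% and 4.34% of random lists held as many. Atp5b, a subunit of ATP synthase, stood at 6.84-fold and 10.74-fold in peaks that did not overlap, although the control peak overlapped an induced promoter peak assigned to Mir677 (8.59-fold). Ndufa10 stood at 8.80-fold in the control list, and Ndufv1 at 10.07-fold and Ndufa1 at 8.59-fold in the induced list. Chromatin and nuclear metabolic enzymes held 6 and 4 of 24, with Acly, an enzyme that makes acetyl-CoA, in both lists (7.33-fold and 10.74-fold). As many were found in 0.83% and 8.80% of random lists. Kdm6b (8.30-fold) in the control list and Kmt2a and Tet1 (9.66-fold each) in the induced list were further members. With centres within 1 kb of the start site the control count was 2, reached by 34.4% of random lists, and at a −log10 p of at least 10 it was 0.

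Cytosolic ribosomal protein genes lay above random lists, with promoter peaks at 10 of 82 in the control and 23 of 82 in the induced list. Random lists averaged 4.13 and 6.21, and 0.77% and 0% of them held as many. Rpl15 (78.39-fold), Rpl32l (28.99-fold), Rpl36a (25.77-fold) and Rps29 (25.19-fold) led the induced list. Their centres lay at 1906, 183, 1644 and -235 bp from the start site, where negative values lie upstream. At a −log10 p of at least 10 the control count was 0. The count in the induced list was 9 at a −log10 p of at least 10 and also 9 with centres within 1 kb of the start site. Olfactory receptor genes lay below random lists, with 24 and 40 of 1111 against 47.1 and 81.6. Olfr66 (35.43-fold, over a pseudogene), Olfr126 and Olfr1434 (11.81-fold each) and Olfr259 (10.74-fold) were members in the induced list, chosen by fold over both lists, which favours the list of lower background.

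Phototransduction genes held promoter peaks at 5 of 35 in the control and 2 of 35 in the induced list, against 2.42 and 2.52 in random lists. Unc119 (9.77-fold) and Rom1 (7.33-fold) were listed in the control, and Rp1 and Cngb1 (12.89-fold each, the latter over a pseudogene) in the induced list. None of the 35 held an exon or promoter peak of at least 20-fold (upper limit 9.89%). Retinal transcription factors held 2 of 25 in each list, Rax (4.89-fold) and Atoh7 (4.40-fold) in the control and Sox2 (13.53-fold) and Isl1 (8.59-fold) in the induced list. Any assigned peak was found at 16 and 20 of these 25 genes, a count reached by 0.08% and 0.01% of random lists. Such assignment favours genes with long intergenic neighbourhoods, which were not matched.

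VEGF and hypoxia genes held promoter peaks at 1 of 36 in the control, Epas1 (5.86-fold), and 3 in the induced list, Vegfa, Egln1 and Pdgfb (8.59-fold each), against 2.49 and 2.60 in random lists. Antioxidant genes held 2 and 3 of 21, with Gpx1 (6.39-fold and 127.78-fold) and Nqo1 (6.35-fold and 6.44-fold) in both and Sqstm1 (6.38-fold) in the induced list. The Gpx1 peaks did not coincide, with centres at 984 bp from the start site in the control and at -1958 bp in the induced list, where negative values lie upstream. The induced peak (108336416 to 108337828) lay wholly outside Gpx1 (108339080 to 108340342). Whether that peak lay inside a neighbouring gene was not examined. Complement genes held 0 and 1 of 20, against 1.31 and 1.45 in random lists. Apoptosis genes held 5 and 2 of 22, a count reached by 1.65% and 48.01% of random lists. With centres within 1 kb of the start site the control count was 3, reached by 8.04%, and at a −log10 p of at least 10 it was 0. Members included Trp53 (7.82-fold) in the control and Bcl2l1 (34.3-fold) and Mcl1 (10.57-fold) in the induced list.

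Cell type markers mostly lay within the range of random lists. Müller glia markers held 1 and 2 of 15, Apoe (5.43-fold) in the control and Vim (69.13-fold) and Hes1 (12.89-fold) in the induced list. Pigment epithelium markers held 2 and 1 of 14, Rgr (6.84-fold) and Pmel (4.63-fold) against Stra6 (8.59-fold). Microglia markers held 2 and 1 of 16, with Cd68 (6.84-fold) in the control. Endothelial and pericyte markers held 0 and 2 of 15, at Vwf (11.29-fold) and Rgs5 (6.44-fold). Bipolar markers held 0 and 1 of 13 (Isl1), amacrine and ganglion markers 0 of 17 in both lists, and liver markers 1 and 0 of 16 (Apoa2, 5.38-fold).

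**Figure D4:**
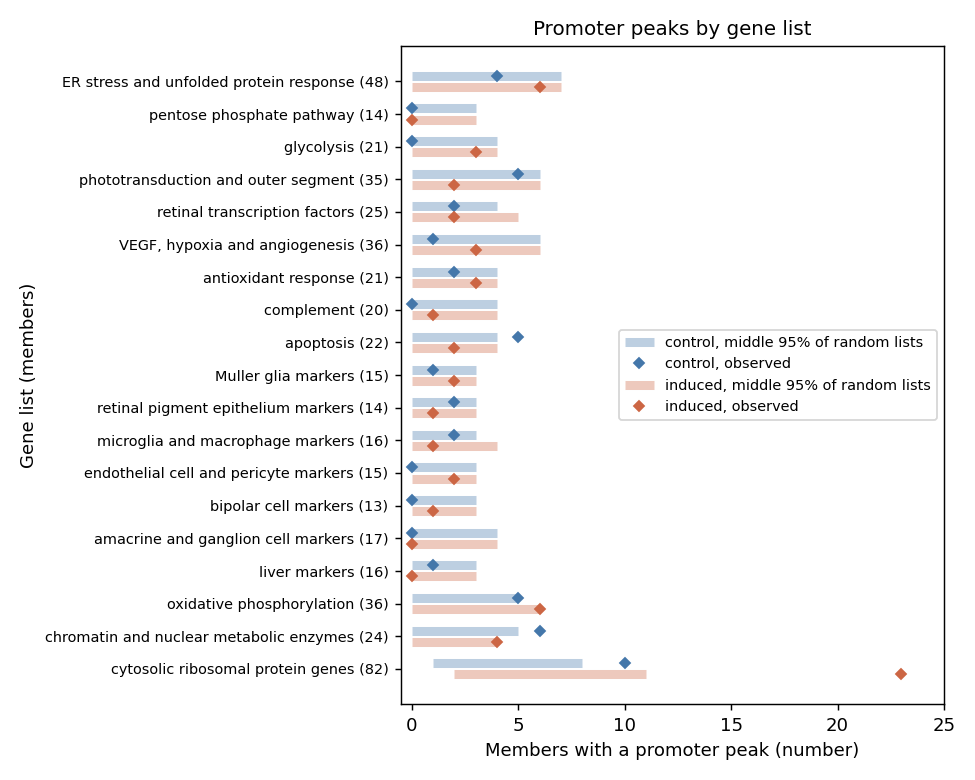
Number of members with a promoter peak in each gene list (diamonds) and the middle 95% of 10000 random lists matched on gene length (bars), for control and induced; olfactory receptors are left out for scale. Ribosomal protein genes lay above their bars, with 10 control and 23 induced members of 82.

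Few positions were listed in both conditions. The pairs with the highest lower fold were a site on chromosome 12 (23477717 to 23478575, nearest gene 2410018L13Rik; 27.86-fold in control and 64.43-fold in induced), the pseudogene Gm6789 near Txnl1 (18.57-fold and 456.36-fold), the Sspn promoter (17.41-fold and 37.37-fold), the Ubb promoter (15.74-fold and 292.07-fold) and the pseudogene Gm13456, nearest Ppp6c (15.64-fold and 374.75-fold). In all, 498 control peaks (2.73%, 2.5 to 2.97) overlapped 503 induced peaks (1.63%), against a mean of 291.5 and a highest of 332 under random placement, a ratio of 1.71. Of induced peaks of at least 100-fold, 48 of 191 (25.1%) overlapped a control peak, and of those under 20-fold 401 of 29718 (1.35%). Across the 505 pairs, which are not independent replicates and whose folds rest on different backgrounds, the folds had a Spearman correlation of 0.21 and a Pearson correlation of 0.36, and over the 402 pairs under 20-fold in the induced list the Spearman correlation was 0.087. At a −log10 p of at least 10, 33 of 153 control peaks (21.6%) overlapped one of 1868 induced peaks, against 0.3 at random. Of the 15 control peaks of highest fold, 13 overlapped an induced peak, and 5 of those 13 lay at pseudogenes. The overlap was 25 of the top 50 and 37 of the top 300 (12.3%).

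**Figure D5:**
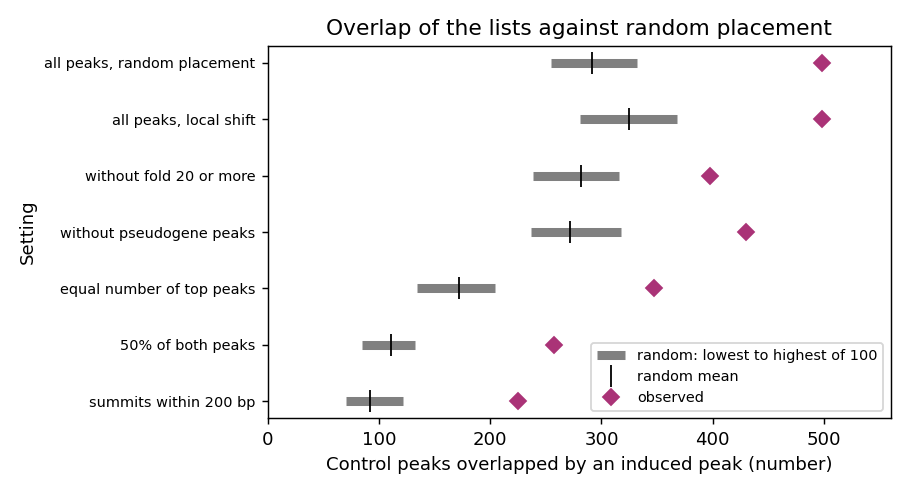
Number of control peaks overlapped by an induced peak (diamonds) for each setting, with the lowest to highest (grey bars) and mean (ticks) of 100 random placements or local shifts. All peaks gave 498 against a random mean of 291.5.

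Unshared control peaks of the highest fold were at the promoters of Ftl1 (16.62-fold), Det1 (11.73-fold) and Mir692-3 (11.24-fold, over the pseudogene Ftl1-ps1). Others were upstream of Tmem223 (13.2-fold) and near Arf1 (11.73-fold). In the induced list the unshared peaks of highest fold lay near Cinp (385.49-fold), Frem2 (303.88-fold), Nucb2 (282.41-fold), Lhfpl3 (280.26-fold) and Cxcr4 (253.41-fold), and all 5 overlapped pseudogenes. By gene, 1696 had a promoter peak in the control list, 1905 in the induced list and 165 in both, against 123.2 for independent lists. A peak missing from a list is not shown to be unbound, since the libraries were called separately and their depth was unknown.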

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

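No paired analysis was possible because each condition had 1 ChIP library, and leaving out a replicate was not possible for the same reason. At a −log10 p of at least 10, the lists held 153 control and 1868 induced peaks, promoter shares of 18.3% and 11.5%, 33 overlapping control peaks at 110 times random, 35 and 229 genes with a promoter peak and 6 in both, and ER stress counts of 0 and 1; the construction leaves fewer peaks. With centres within 1 kb of a start site, the promoter shares were 5.43% and 3.36%, the genes 1091 and 1117 with 62 in both, and the induced ER stress count 3. Within 3 kb the shares were 10.6% and 7.88%, with 255 genes in both. Equal numbers of top peaks gave an induced promoter share of 6.14%, 1220 induced genes and 109 in both. Overlap of 50% of both peaks left 257 control peaks and summits within 200 bp left 225, as stricter definitions do. The control promoter share stayed above the induced share, and the overlap above random placement, in every setting run. The ER stress count of 6 in the induced list was reached by 2.35% of random lists with equal numbers of top peaks and by 13.5% with all peaks. The other settings chosen beforehand moved none of the main results. Over all settings chosen beforehand, 25 values of the main results moved and 64 stayed within their limits. A false discovery rate listed as 0, chosen after seeing the data, left 55 control and 2078 induced peaks, promoter shares of 21.8% and 11.2%, 30 overlapping control peaks at 500 times random, 14 and 248 genes with 6 in both, and ER stress counts of 0 and 1. The other alternatives chosen after seeing the data, without pseudogene peaks, without peaks of at least 20-fold and with local shifts, left the main results within their limits, with overlap at 1.58, 1.42 and 1.53 times random. Restriction to the autosomes, X and Y removed no peak. Among counts of single gene lists, 65 moved and 295 stayed under settings chosen beforehand, and 31 moved and 77 stayed under those added later. Unknown total depth limits every comparison of the number of peaks.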

Other observations

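The tests of explanations here were chosen only after the results had been seen, except the comparison of pseudogene parent genes, whose bounds were written before its value was computed but after the pattern was known, and the overlap at a −log10 p of at least 10, a setting chosen before the data were examined, whose bound was written later. Each describes 1 library per condition.

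The peak with the most tags lay at the ribosomal RNA gene Rn45s (2937 tags, 3.33-fold) in the control list and at a site nearest Gm3629 (9070 tags, 2.87-fold) in the induced list. Peaks of many tags and low fold were not masked here. The Rn45s site, with 2876 tags at 4.73-fold in the induced list, was counted among the shared pairs. Counting any assigned peak, several lists lay above most random lists in at least 1 condition. Bipolar markers had 5 of 13 in the control and 11 of 13 in the induced list, reached by 55.8% and 0.45% of random lists, and amacrine and ganglion markers 8 and 13 of 17 (20.9% and 0.57%). Glycolysis genes had 5 and 14 of 21 (89.6% and 3.02%), Müller glia markers 9 and 9 of 15 (1.3% and 10.5%), apoptosis genes 14 and 14 of 22 (0.76% and 8.56%), and ribosomal protein genes 25 and 39 of 82 (6.31% and 0.5%). With equal numbers of top peaks, the induced bipolar count was 8, reached by 5.82%. Assignment favours genes with long intergenic neighbourhoods, which were not matched.

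Induced peaks of high fold lay at pseudogenes and exons, with 79.2% (72.8 to 84.5) of the exon or intron peaks of at least 20-fold outside pseudogenes in exons, against 8.07% of weaker peaks. A candidate explanation is DNA derived from transcripts in the induced ChIP library: 23.7% (16.4 to 33.1) of 97 parent genes of pseudogenes under such a peak held one themselves, outside pseudogenes, against 4.84% (2.79 to 8.27) of 248 other parents, although tags shared between a gene and its copies, and the number of copies, were not separated from this. Binding around start sites was examined through the promoter peaks of at least 20-fold outside pseudogenes. Of these, 82.2% (73.6 to 88.4) were centred downstream of the start site, against 54.7% of weaker ones. The bound for this test was set after the Atf4 positions were seen. The test shows a downstream side but cannot decide on binding, because every promoter peak was by definition centred within 2 kb of a start site. Promoters held 12.8% of all induced peaks of at least 20-fold and 5.52% of the weaker ones. Binding that arises only on induction was examined through the control list, where 26% of the 50 strongest peaks lay at pseudogenes. Over all control peaks the share was 1.61%, against 1.43% under random placement. Of the 1073 induced peaks of at least 20-fold, 102 (9.51%) overlapped a control peak. Whether the high induced peaks arose only on induction stays open, since a peak missing from a list is not shown to be unbound. Whether such transcripts came from the retina itself cannot be told apart: 0 of 35 phototransduction genes held an exon or promoter peak of at least 20-fold, but the upper limit of 9.89% lies above the lower limit of 5.88% for ribosomal protein genes, and a stricter bound tried after this value was known was discarded.

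Few peaks were shared between the lists. Outside pseudogenes, exons and promoters and under 20-fold, overlap was 1.48 times random placement and 1.37 times local shifts, so many of these peaks may be calls at the level of background. The bound of 1.5 was set after related values were seen and the value lies just under it, and 323 overlaps still exceeded the highest random count of 257. Whether weak peaks hide a mostly shared set of strong peaks cannot be told apart, because the answer turns on the threshold: 21.6% (15.8 to 28.7) of control peaks with a −log10 p of at least 10 overlapped such an induced peak, 110 times random, and 30 of 55 (54.5%, 41.5 to 67.0) with a false discovery rate listed as 0 did. A real relocation of binding on induction was not tested and stays open.

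ER stress genes held high induced peaks at Atf4, Hsp90b1 and Hspa5. As many members were found in 1.71% of random lists, but ribosomal protein genes held such peaks at 10.98% (5.88 to 19.6) against 6.25% (2.15 to 16.8) of ER stress genes. Whether the peaks go with ER stress genes in particular or with abundant transcripts cannot be told apart, because random lists were not matched on transcript abundance. A biological link between transketolase and these genes stays open as a hypothesis.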
